A study of Homo sapiens with 3 samples.

How the data were processed

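Transcript levels were measured by RNA sequencing in 3 samples of the C28/I2 chondrocyte line grown as spheroids with 0.5% DMSO for 48 h; RNA was extracted with Trizol and libraries were made with an in-house kit of the sequencing company, per the labels' protocols. The submitters' processing notes name Bowtie2 version 2.2.5, RSEM version 1.2.12, DESeq2 version 1.4.5 and the genome build GRCh38.p13, without stating which step each served. The strandedness of the libraries and the choice of RNA with or without a poly(A) tail are not given in the sources used here.

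The authors deposited 1 table of 19215 genes named by symbol. Expression values are FPKM to 2 decimals for each library, per the file headers. The log2 fold change between monolayer and spheroid cultures, its p-value and its adjusted p-value (q-value) come from the authors' DESeq2 comparison, per the file headers. Adjusted values equalled a Benjamini-Hochberg adjustment of the deposited p-values to within 1.3e-15. A positive fold change means higher in spheroids: of 358 genes at 0 in the 3 spheroid libraries with a fold change, 356 had one below 0 and 2 above. Fold changes were present for 18467 genes and absent for 748, of which 737 were at 0 in the 3 spheroid libraries. The table also has 3 FPKM columns of single libraries, named as monolayer in the header, that match no listed sample. They were used in no step, so the authors' comparison was not recomputed. Groups and replicate numbers come from the labels.

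Because FPKM depends on gene length and the library total, low values were examined for steps of 1 read. The median log2 ratio between libraries for genes from 0.3 to 1.5 FPKM was -0.013 for replicates 1 and 2 and 0 for the other pairs. A median can neither show nor exclude such steps, so depth is unknown and no interval or detection floor is given. FPKM values were used as deposited, since scale factors by median ratio to the geometric mean were 1.00, 0.995 and 1.01. Levels are means with SD over the 3 spheroid libraries, and correlations use log2(FPKM + 1), with a pseudocount of 1, over genes above 0 in any library. With 2 decimals, values near 0 are coarse. The 3 libraries differed for most genes, and none was counted as a copy of another. Genes with near-identical copies share reads in ways the deposited values do not show: 12 genes at 1 FPKM or more, in 6 sets, had values identical to another gene in the 3 libraries, and 5 of them were past the threshold.

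A gene was called higher or lower at an authors' adjusted p under 0.05 with an absolute log2 fold change of at least 1. The 31 gene lists (582 entries), among them markers of other cell types, and the rule for named genes were fixed before the data were examined. For each of 30 lists with at least 3 tested members, the median of the authors' log2 fold changes was set against 10000 random lists of the same size, matched on deciles of the mean spheroid level. The permutation p is two-sided, its smallest possible value is 0.0002, and Benjamini-Hochberg adjustment was made over the 30 lists with a threshold of 0.05. As alternatives, limma's cameraPR (limma 3.58.1, R 4.3.3) was run with a preset correlation of 0.01 and with a correlation estimated from the spheroid libraries, and Fisher's exact test compared called members with other genes. With the estimated correlation, matrix-degrading enzymes, inflammatory genes, immune cell markers, replication-dependent histones and mitosis kept an adjusted p under 0.05. The list test was tested on simulated data from the 18467 genes: it called 5 of 5 lists of 20 genes shifted by 1 on the log2 scale, 5 of 5 shifted by 2 and 2 of 100 unshifted lists. The simulated members were drawn at random and independent, unlike the correlated members of the fixed lists. These counts therefore do not give the rate of false calls for the fixed lists.

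The named genes are the 12 with the smallest adjusted p in each direction, up to 4 members of each list past the threshold with the largest fold change in each direction (those higher with a spheroid mean of at least 1 FPKM), 12 genes fixed in advance and the 10 with the highest spheroid level; others are said to have been chosen after their values were seen. Not every gene the rule gives is printed, and some are not reported here. Other alternatives were an adjusted p under 0.01, no minimum fold change, a minimum of 2, genes with at least 1 FPKM, fold changes centred on the median, unmatched random lists, leaving out each replicate, median-ratio scaling and a pseudocount of 0.1. Of the symbols, 18517 matched the reference table of gene names; no coordinates are given. Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.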

Results

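RNA sequencing measured transcript levels in C28/I2 cells, a human chondrocyte line immortalised with a viral large T antigen. Chondrocytes are the cells that make and maintain the matrix of cartilage. The 3 samples form 1 labelled group of spheroid cultures, in which the cells grow as aggregates, exposed for 48 h to 0.5% DMSO, a common solvent for drugs. The labels do not say whether the 3 samples came from separate cultures, so the spread between them may be technical. Monolayer cultures of the same line enter through the authors' deposited table of fold changes between the culture forms, and their single libraries were not analysed here. How the monolayer cultures were treated is not given in the sources used here.

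The FPKM values of the spheroid libraries summed to 571705, 581522 and 623496 in replicates 1, 2 and 3. They listed 17230, 17207 and 17240 genes above 0, and 12406, 12383 and 12416 genes at 1 FPKM or more. The total read count behind these values is unknown, so no counting interval is given. Across 18120 genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.997 for replicates 1 and 2, 0.994 for replicates 1 and 3, and 0.996 for replicates 2 and 3. The median coefficient of variation was 8.37% over the 12410 genes with a mean of at least 1 FPKM. It was 15.1% in the lowest decile of these genes by mean level and 7.04% in the highest. No pair of libraries held identical values, and 859, 632 and 665 of the 18120 genes had equal values to 2 decimals in the 3 pairs.

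Among the genes in the authors' deposited table, the most abundant spheroid transcripts came from MT2A, a metal-binding metallothionein, and FTH1, the ferritin heavy chain that stores iron. They averaged 15556 ± 2036 and 12050 ± 804 FPKM (SD, n = 3). The glycolytic enzyme gene GAPDH followed at 6196 ± 340 FPKM, TMSB10, encoding an actin-binding thymosin, at 5753 ± 508 FPKM, and the galectin gene LGALS1 at 4944 ± 564 FPKM (SD, n = 3). GAGE12B, a cancer-testis antigen gene, and MTRNR2L2, a nuclear gene resembling mitochondrial ribosomal RNA, were listed at 9745 ± 980 and 8682 ± 482 FPKM (SD, n = 3). Both have near-identical copies with which they can share reads, so their levels are uncertain. The fibronectin gene FN1 reached 3393 ± 766 FPKM and CHI3L1, encoding a secreted chitinase-like glycoprotein of chondrocytes, 3175 ± 212 FPKM (SD, n = 3).

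The comparison between culture forms asks which genes differ when the line grows as spheroids rather than as a monolayer. Genes of mitosis and DNA replication were lower in the spheroids without exception: all 24 tested members of each list passed the threshold, with median log2 fold changes of -3.60 and -2.80 in the authors' deposited table. Matrix-degrading enzymes, inflammatory cytokines, interferon-stimulated genes and hypoxia-inducible genes were higher, with medians of 1.56, 2.5, 2.34 and 1.83 in the authors' deposited table. Cholesterol synthesis genes and targets of the mechanosensitive YAP and TAZ coactivators were lower, with medians of -1.72 and -1.02 in the authors' deposited table. Each of these 8 lists had a permutation p of 0.0002, the smallest that 10000 random lists can give, and an adjusted p of 0.000667. With an estimated correlation the adjusted p was 0.0999 for DNA replication, 0.0517 for interferon-stimulated genes, 0.131 for hypoxia-inducible genes, 0.119 for cholesterol synthesis and 0.104 for YAP/TAZ targets (limma's cameraPR).

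In the authors' deposited table, 3841 of 18467 tested genes (20.8%) passed an adjusted p of 0.05 with an absolute log2 fold change of at least 1. Of these, 2117 were higher and 1724 lower in the spheroids. Large changes were mostly upward: 276 of them had a log2 fold change of 4 or more, and 32 of -4 or less. The median log2 fold change of all tested genes was 0.04. If the spheroid libraries did not come from separate cultures, the adjusted p-values behind these counts do not measure the spread between cultures. Of 30 gene lists tested, 7 lay higher and 7 lower than random lists of genes with like expression; with an estimated correlation 4 of the higher lists and 1 of the lower kept an adjusted p under 0.05 (limma's cameraPR). The number of members past the threshold, adjusted over the list alone, equalled that over all genes for 28 of the 30 lists; the hypoxia-inducible and SDF-1 lists, below, are the exceptions.

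**Figure D1:**
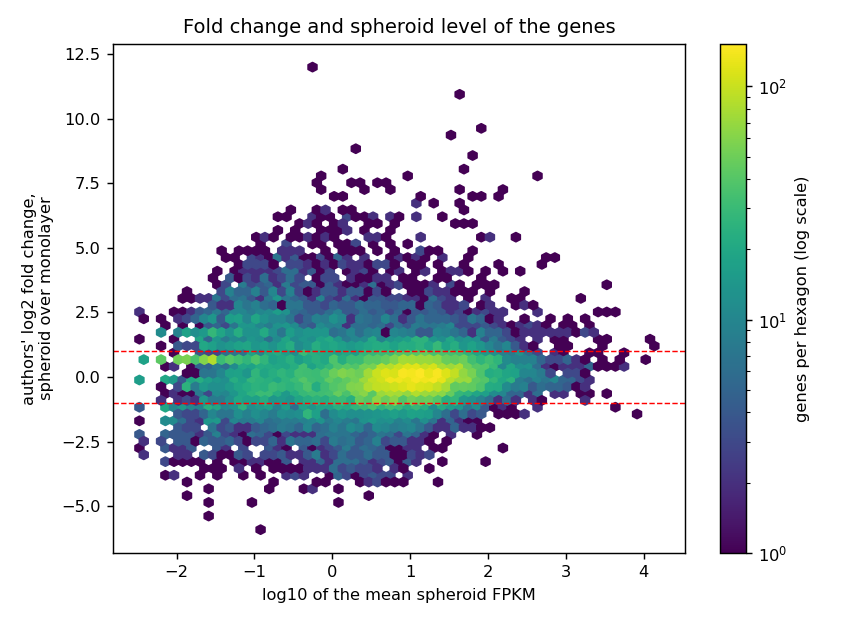
Each hexagon counts genes by the log10 of their mean FPKM over the 3 spheroid libraries (horizontal axis) and the authors' log2 fold change of spheroid over monolayer (vertical axis), with colour for the number of genes on a log scale and dashed lines at log2 fold changes of 1 and -1. Genes at 0 in the 3 spheroid libraries are not drawn. More genes lie far above the upper line than far below the lower one. Of all genes past the threshold, drawn or not, 276 lie at 4 or more and 32 at -4 or less.

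Matrix-degrading enzymes rose, with 11 of 20 members higher, 1 lower and 8 not past the threshold. The collagenase genes MMP13 and MMP1 had log2 fold changes of 5.50 and 4.75 in the authors' deposited table, which are 45.4 and 27.0 times the monolayer level, each with an adjusted p listed as 0. MMP10, encoding a stromelysin, stood at 6.61, the gelatinase gene MMP9 at 5.47 and the elastase gene MMP12 at 4.13 in the authors' deposited table. The member that fell was ADAMTS1, a metalloproteinase gene, at -2.34 in the authors' deposited table (adjusted p = 9.46e-16 in the DESeq2 comparison). Spheroid levels were 679 ± 84.9 FPKM for MMP1, 285 ± 27.0 for MMP12, 249 ± 33.8 for MMP13 and 115 ± 30.9 for MMP9 (SD, n = 3). This list kept an adjusted p of 0.0247 with an estimated correlation.

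Inflammatory cytokines and NF-kB targets rose, with 16 of 22 members higher, none lower and 6 not past the threshold. The authors' deposited table gave log2 fold changes of 6.27 for the chemokine gene CCL20, 5.81 for the cytokine gene IL1B, 5.02 for the adhesion molecule gene ICAM1 and 4.91 for the cytokine gene IL6. The list's adjusted p was 0.0318 with an estimated correlation. Outside the list, the authors' deposited table had CCL7, a monocyte chemoattractant, at 4.72, TREM1, an amplifying receptor of myeloid cells, at 7.0, CHI3L1 at 3.51 and NAMPT, the rate-limiting enzyme of NAD salvage, at 2.89. CCL7 averaged 615 ± 63.2 FPKM, NAMPT 266 ± 21.2, TREM1 82.6 ± 7.18 and IL1B 39.1 ± 5.83 (SD, n = 3). Over the list members at 1 FPKM or more, the median deviation of log2(FPKM + 1) from the mean of the 3 libraries was -0.21 in replicate 1, 0.06 in replicate 2 and 0.10 in replicate 3. Replicate 1 had negative medians, too, over the matrix-degrading (-0.11), interferon-stimulated (-0.11) and hypoxia-inducible (-0.14) lists.

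Interferon-stimulated genes rose, with 20 of 22 members higher, none lower and 2 not past the threshold (permutation adjusted p = 0.000667; adjusted p = 0.0517 with an estimated correlation). RSAD2, encoding the antiviral protein viperin, had a log2 fold change of 5.93 in the authors' deposited table, or 61.0 times the monolayer level. IFIT2, whose product binds viral RNA, followed at 5.41, OASL, of the oligoadenylate synthetase family, at 4.43, IFI44L at 3.55 and, outside the list, the interferon-induced GTPase gene GBP2 at 3.60 in the authors' deposited table. IFIT2 averaged 87.9 ± 2.72 FPKM, GBP2 67.1 ± 5.48, OASL 52.6 ± 5.88 and RSAD2 50.0 ± 1.38 (SD, n = 3).

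Markers of immune cells also lay higher than random lists (permutation adjusted p = 0.00109, and adjusted p = 0.0202 with an estimated correlation). Of 14 members, 4 were higher, none lower and 10 not past the threshold. In Fisher's exact test of called members this list did not pass (adjusted p = 0.238; 0.0030 to 0.238 over the 6 alternatives). CD68, a lysosomal glycoprotein gene used as a macrophage marker, had a log2 fold change of 2.16 in the authors' deposited table, against 1.88 and 2.14 for the T-cell receptor complex genes CD3D and CD3E. The fourth was CD163, chosen after its values were seen, at 2.58 in the authors' deposited table. CD68 averaged 702 ± 41 FPKM, CD3D 32.6 ± 3.31, CD3E 1.09 ± 0.0693 and CD163 0.30 ± 0.070 (SD, n = 3).

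Hypoxia-inducible genes rose, with 20 of 23 members higher, 1 lower and 2 not past the threshold; adjusted over the list alone, 21 were higher (permutation adjusted p = 0.000667; adjusted p = 0.131 with an estimated correlation). CA9, a carbonic anhydrase gene, and NDRG1, a stress-responsive gene, had log2 fold changes of 4.35 and 4.25 in the authors' deposited table. DDIT4, an inhibitor of mTOR signalling, stood at 3.24, the MYC antagonist gene MXI1 at 2.99 and the angiogenic growth factor gene VEGFA at 1.83 in the authors' deposited table. STC2, a secreted glycoprotein gene, fell by 1.81 on the log2 scale in the authors' deposited table. NDRG1 averaged 502 ± 39.7 FPKM, CA9 148 ± 24.2 and VEGFA 147 ± 16.8 (SD, n = 3). Glycolysis enzymes did not pass as a list (5 of 17 higher, none lower; 14 higher and 1 lower by the DESeq2 adjusted p alone; permutation adjusted p = 0.153), although ENO2 and PGK1, encoding an enolase and phosphoglycerate kinase, had log2 fold changes of 1.99 and 1.59 in the authors' deposited table. With random lists matched on the midpoint level of both cultures, chosen after the data were seen, the glycolysis list passed (permutation adjusted p = 0.0227; 0.0227 to 0.746 over the 6 alternatives).

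Lysosome and autophagy genes rose as a list, with 7 of 21 members higher and none lower (median log2 fold change 0.89 in the authors' deposited table; permutation adjusted p = 0.00323; adjusted p = 0.238 with an estimated correlation). At a preset correlation it did not pass either (adjusted p = 0.106, limma's cameraPR). Among them, the authors' deposited table listed WIPI1, an autophagosome formation gene, at 1.49, TFEB, a transcription factor of lysosomal genes, at 1.34, and the protease genes CTSA and CTSZ at 1.21 and 1.17.

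**Figure D2:**
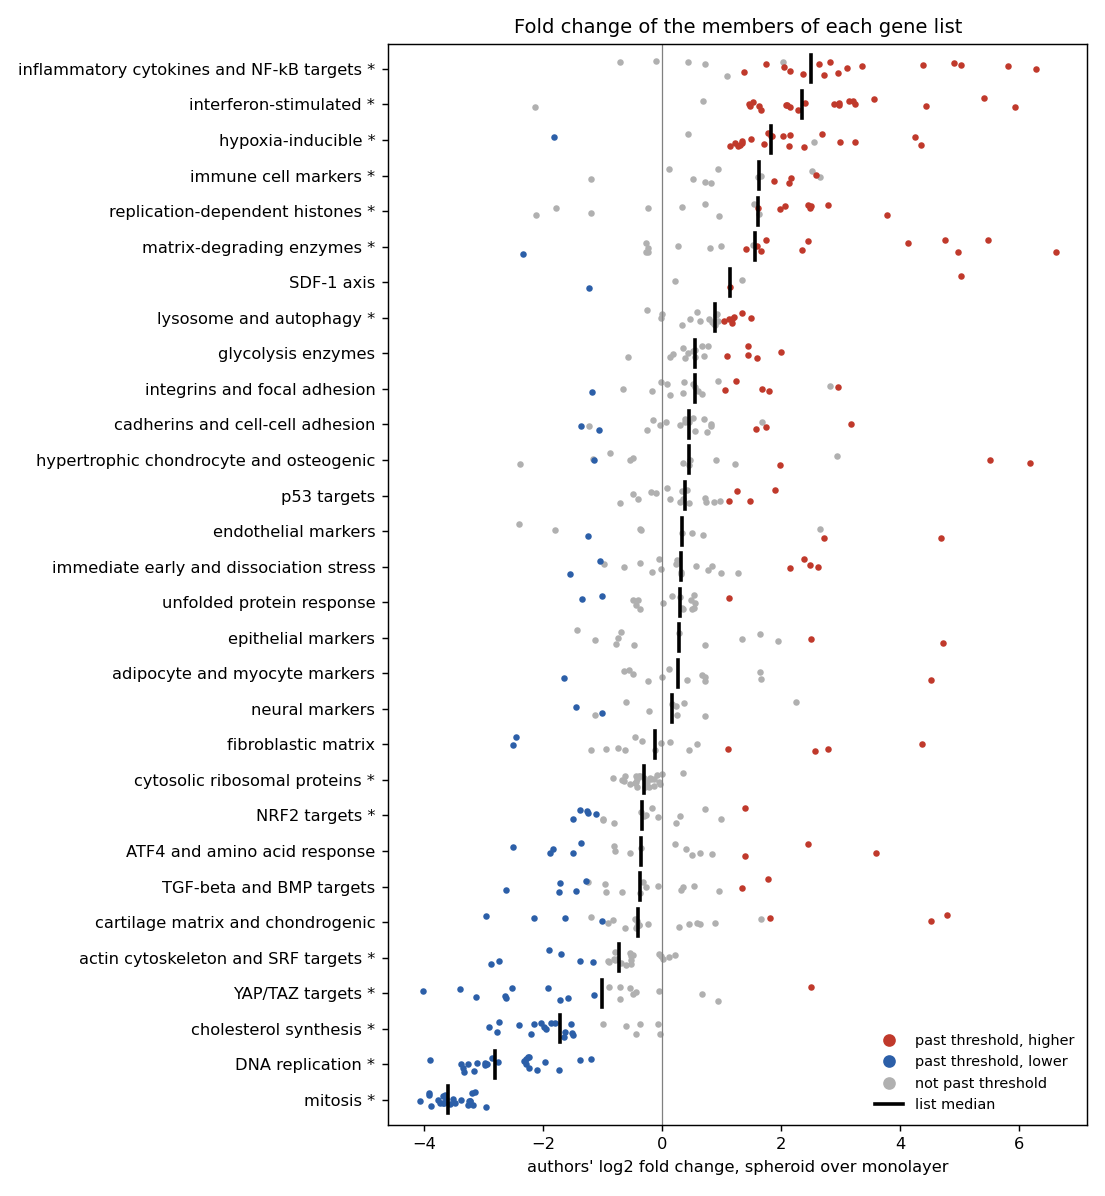
Each point is a gene of a fixed list at its log2 fold change of spheroid over monolayer in the authors' deposited table (horizontal axis), coloured by whether it passed the threshold as higher (red), lower (blue) or not at all (grey), with black bars for list medians. Asterisks mark the 14 lists past the permutation test; the median lies at -3.60 for mitosis and at 2.5 for inflammatory genes.

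The 24 mitosis genes fell together, with KIF23, a kinesin gene of cytokinesis, at -4.07, the mitotic kinase gene AURKB at -3.92, TOP2A, a DNA topoisomerase gene, at -3.92 and CDC20, an activator of the anaphase-promoting complex, at -3.89 in the authors' deposited table. The list's adjusted p was 0.0318 with an estimated correlation. The proliferation marker MKI67 stood at -3.77 in the authors' deposited table, 13.7 times lower than in monolayer. Among the genes with the smallest adjusted p were also the kinesin gene KIF18B at -4.71, TROAP at -4.54, IQGAP3 at -4.20, HJURP, the chaperone of the centromeric histone, at -3.76, and TACC3 at -3.36 in the authors' deposited table. The genes remained detectable in the spheroids, at 9.42 ± 1.69 FPKM for AURKB, 5.0 ± 2.06 for TOP2A and 3.96 ± 1.15 for MKI67 (SD, n = 3). Over mitosis members at 1 FPKM or more, the median deviation of log2(FPKM + 1) from the mean of the 3 libraries was 0.31 in replicate 1, -0.12 in replicate 2 and -0.19 in replicate 3. Replicate 1 had positive medians over the DNA replication (0.16), cholesterol synthesis (0.14), YAP/TAZ (0.19) and actin (0.12) lists as well.

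The 24 DNA replication genes fell as well (permutation adjusted p = 0.000667; adjusted p = 0.0999 with an estimated correlation). RRM2, a ribonucleotide reductase subunit gene, stood at -3.90, the origin licensing factor gene CDT1 at -3.38, UHRF1, of maintenance DNA methylation, at -3.35 and the helicase component gene CDC45 at -3.33 in the authors' deposited table. The helicase gene RECQL4 and the Fanconi anaemia DNA repair gene FANCA, outside the list, stood at -3.67 and -3.89 in the authors' deposited table.

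Replication-dependent histone genes went the other way, with 8 of 17 tested members higher, none lower and 9 not past the threshold (median 1.61 in the authors' deposited table; permutation adjusted p = 0.00109; adjusted p = 0.0409 with an estimated correlation). H2AC13 stood at 3.79, H3C10 at 2.79, H2BC5 at 2.5 and H2AC6 at 2.48 in the authors' deposited table. H2AC6 averaged 107 ± 16.5 FPKM and H2BC5 70.8 ± 8.61 (SD, n = 3). Histone copies are near-identical and can share reads, so the values of single copies are uncertain.

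Cholesterol synthesis genes fell, with 16 of 22 members lower, none higher and 6 not past the threshold (permutation adjusted p = 0.000667; adjusted p = 0.119 with an estimated correlation). DHCR7, encoding the last enzyme of one branch of the pathway, stood at -2.90, the sterol isomerase gene EBP at -2.77 and the sterol oxidase gene MSMO1 at -2.41 in the authors' deposited table. DHCR7 averaged 11.2 ± 3.20 FPKM and EBP 12.1 ± 1.70 (SD, n = 3).

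Targets of YAP and TAZ fell, with 10 of 20 members lower, 1 higher and 9 not past the threshold (permutation adjusted p = 0.000667; adjusted p = 0.104 with an estimated correlation). The matricellular protein genes CCN1 and CCN2 stood at -4.02 and -3.13, the ankyrin repeat gene ANKRD1 at -3.40 and TGFB2 at -2.65 in the authors' deposited table, and IGFBP3, encoding an insulin-like growth factor binding protein, was the member that rose, at 2.5. CCN1 was listed at 38.5 FPKM in replicate 1, against 11.7 and 11.5 in replicates 2 and 3, so that its mean of 20.5 became 11.6 without replicate 1. ANKRD1 was at 48.0 FPKM in replicate 1, against 17.4 and 14.6, and its mean of 26.7 became 16.0 without replicate 1.

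Actin cytoskeleton and SRF target genes fell as a list, with 6 of 24 members lower and none higher (median -0.72 in the authors' deposited table; permutation adjusted p = 0.000667; adjusted p = 0.580 with an estimated correlation). The smooth muscle contractile genes CNN1 and TAGLN led them at -2.88 and -2.75 in the authors' deposited table. NRF2 targets lay below random lists, with 5 of 18 lower and 1 higher (median -0.33 in the authors' deposited table). Their permutation adjusted p was 0.0197, and the adjusted p was 0.742 with an estimated correlation. Among them, the quinone reductase gene NQO1 stood at -1.50 and the thioredoxin reductase gene TXNRD1 at -1.38, with FTH1 higher at 1.39. Cytosolic ribosomal protein genes had a median of -0.30 in the authors' deposited table with none of 25 past the threshold for single genes (15 lower and 1 higher by the DESeq2 adjusted p alone), and lay below random lists (permutation adjusted p = 0.0025; adjusted p = 0.781 with an estimated correlation). In Fisher's exact test the actin and NRF2 lists did not pass (adjusted p = 0.0992 for both), nor did the ribosomal protein list (0.402). The random lists were matched on the spheroid level, which also enters the fold change. Their medians were 0.14 for NRF2 targets and 0.22 for ribosomal proteins, against 0.04 over all tested genes. With unmatched random lists the NRF2 and ribosomal protein lists did not pass, so their shift depends on the matching.

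Cartilage matrix and chondrogenic genes did not pass as a list (permutation adjusted p = 0.159): 3 of 24 members were higher, 4 lower and 17 not past the threshold. In the authors' deposited table the list's median was -0.41 and its mean 0.06, opposite in sign. The proteoglycan gene ACAN, at -2.16, the receptor gene FGFR3, at -2.96, and the link protein gene HAPLN1, at -1.63, were lower in the authors' deposited table. The members that were higher, chosen after their values were seen, were COL9A1 at 4.79, SOX5 at 4.52 and FMOD at 1.81 in the authors' deposited table. Levels were low throughout: ACAN averaged 0.730 ± 0.0400 FPKM (SD, n = 3), and 5 members of the list reached 1 FPKM. COL2A1, encoding the main collagen of cartilage, was listed at 0.03, 0.01 and 0.01 FPKM in replicates 1, 2 and 3. The chondrogenic transcription factor gene SOX9 averaged 6.71 ± 0.0866 FPKM (SD, n = 3), and its log2 fold change of -0.62 in the authors' deposited table was below the minimum set for a call.

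Hypertrophic chondrocyte and osteogenic genes did not pass as a list (3 of 15 higher, 1 lower; permutation adjusted p = 0.369). Beside MMP13, the bone sialoprotein gene IBSP stood at 6.18 and MEF2C, chosen after its values were seen, at 1.97, the phosphatase gene PHOSPHO1 at -1.14, the transcription factor gene RUNX2 at 0.45 and the hypertrophic collagen gene COL10A1 at -0.48 in the authors' deposited table, of which RUNX2 and COL10A1 were not past the threshold. RUNX2 averaged 11.4 ± 0.663 FPKM, IBSP 1.48 ± 0.427 and COL10A1 0.0567 ± 0.0306 (SD, n = 3). Fibroblastic matrix genes did not pass either (4 of 17 higher, 2 lower; permutation adjusted p = 0.369), with a median of -0.12 and a mean of 0.15 in the authors' deposited table. FN1 rose at 2.57, the small proteoglycan genes DCN and LUM at 4.36 and 2.78, the protease gene FAP at 1.10, and THY1 and COL12A1 fell, at -2.46 and -2.51 in the authors' deposited table, while COL1A1, at -0.95, was not past the threshold. COL1A1 averaged 471 ± 28.6 FPKM, DCN 1.48 ± 0.130, LUM 1.89 ± 0.127 and COL12A1 1.92 ± 0.490 (SD, n = 3). THY1 was listed at 0.03 FPKM in each spheroid library, so its fold change rests on values near 0.

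The SDF-1 axis, the chemokine CXCL12 with its receptors and partners, had 2 of 5 members higher and 1 lower (permutation adjusted p = 0.0963, or 0.0484 with midpoint matching and 0.0484 to 0.290 over the 6 alternatives); adjusted over the list alone, 3 were higher. The receptor gene CXCR4 stood at 5.02 in the authors' deposited table, 32.6 times the monolayer level, DPP4, encoding a peptidase that cleaves the chemokine, at 1.14 and HMGB1 at -1.23. CXCL12 itself, at 1.33 with an adjusted p of 0.0522 from the authors' DESeq2 comparison, and the other receptor gene ACKR3, at 0.21, were not past the threshold in the authors' deposited table. CXCR4 averaged 63.4 ± 8.73 FPKM, ACKR3 20.6 ± 1.01 and CXCL12 0.633 ± 0.176 (SD, n = 3).

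**Figure D3:**
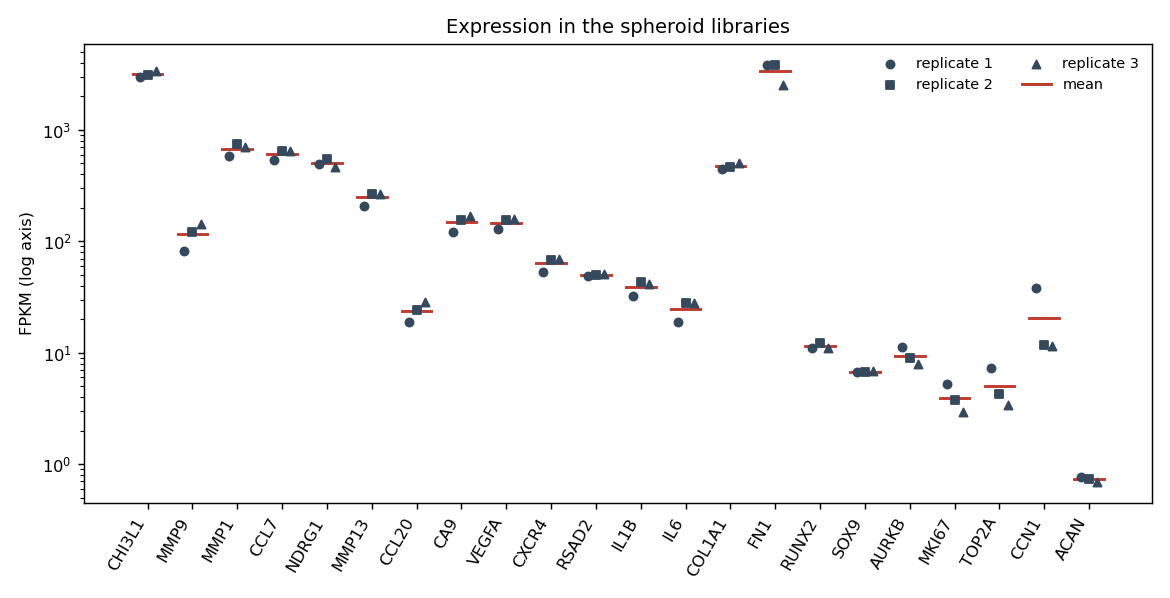
Levels of 22 named genes in the spheroid libraries, in FPKM on a log axis, with a symbol for each of the 3 replicates and a line at their mean. CHI3L1 and FN1 average 3175 and 3393 FPKM while ACAN lies below 1, and replicate 1 stands apart for CCN1 at 38.5 FPKM.

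Signalling and stress lists beyond these did not pass the permutation test, with members going both ways in most. Integrin and focal adhesion genes had 5 of 19 higher and 1 lower (permutation adjusted p = 0.0671, or 0.0198 with midpoint matching and 0.0198 to 0.713 over the 6 alternatives), led by the collagen receptor genes ITGA2 and ITGA10 at 2.95 and 1.80 in the authors' deposited table. Cadherin and cell-cell adhesion genes had 3 of 21 higher and 2 lower (permutation adjusted p = 0.133), with the gap junction gene GJA1 at 3.17 and the N-cadherin gene CDH2 at -1.36 in the authors' deposited table. TGF-beta and BMP targets had 2 of 19 higher and 5 lower (permutation adjusted p = 0.0829), with the inhibitory SMAD gene SMAD6 at -2.62 and ID1 at -1.72 in the authors' deposited table. The ATF4 and amino acid response list had 3 of 17 higher and 5 lower (permutation adjusted p = 0.0671), with the stress transcription factor gene ATF3 at 3.58 and the serine synthesis genes PSAT1 and PHGDH at -2.5 and -1.88 in the authors' deposited table. PSAT1 was listed at 13.2 FPKM in replicate 1, against 2.92 and 3.04 in replicates 2 and 3, so that its mean of 6.37 became 2.98 without replicate 1, and the list's median deviation was 0.14 in replicate 1 and -0.10 in replicates 2 and 3. Immediate early genes had 4 of 21 higher and 2 lower (permutation adjusted p = 0.307), with JUNB at 2.48 and MYC at -1.55 in the authors' deposited table. p53 targets had 4 of 20 higher and none lower (permutation adjusted p = 0.0950), with the pro-apoptotic gene BBC3 at 1.90 in the authors' deposited table, while the unfolded protein response had 1 of 17 higher, the sensor gene ERN1 at 1.13, and MANF and SDF2L1 lower at -1.35 and -1.01 (permutation adjusted p = 0.506).

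Marker lists of cell types other than immune cells did not pass. Endothelial markers had 2 of 11 higher, PECAM1 and KDR, and 1 lower, ESAM (permutation adjusted p = 0.638). Epithelial markers had 2 of 13 higher, KRT5 and ELF3 (permutation adjusted p = 0.638), and adipocyte and myocyte markers 1 of 14 higher, MYOD1, and 1 lower, FABP4 (permutation adjusted p = 0.641). The list of neural markers had 2 of 11 lower, RBFOX3 and ENO3 (permutation adjusted p = 0.698). ENO3 encodes the muscle form of enolase, so it is a poor neural marker, and the list was kept as fixed. PECAM1, KDR, KRT5 and MYOD1 were chosen after their values were seen and averaged 0.657 ± 0.0802, 0.603 ± 0.0907, 0.657 ± 0.164 and 0.393 ± 0.0503 FPKM (SD, n = 3). None of the 13 mitochondrially encoded genes of the fixed list was in the authors' deposited table, so that list is not analysed here. The comparison rests on the authors' fit, which was not refitted because the single monolayer libraries match no listed sample and were left unused. No labelled monolayer sample allows culture form to be separated from any separate handling of the libraries or from the DMSO of the spheroids. The random lists treat genes as independent, so their p-values are too small, and the estimated correlation rests on 3 libraries.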

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

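Matching random lists on the midpoint of both cultures' levels was chosen after the data were seen; the other alternatives were planned. The count of 3841 genes past the threshold (2117 higher, 1724 lower) became 9313 (4795 and 4518) with no minimum fold change and 1498 (933 and 565) with an absolute log2 fold change of at least 2, because these settings admit smaller or only larger changes. It stayed within 1.5 times at an adjusted p under 0.01 (3526), over genes at 1 FPKM or more (2799) and with centred fold changes (3860). Of 7 lists higher and 7 lower, 4 and 1 passed with cameraPR at an estimated correlation, 5 in all; the statistic, the matching and the correlation, which rests on 3 libraries, change together there, and the cause was not tested. Fisher's exact test, which counts only members past the threshold, called 4 lists lower. None of the 25 ribosomal protein genes was past the threshold, so that list could not be called lower there. The cause for the actin and NRF2 lists was not tested. No list that passed reversed under the 6 alternatives. NRF2 targets and ribosomal proteins were lost with unmatched lists (adjusted p = 0.167 and 0.164), at the preset correlation (0.213 for both), in Fisher's exact test (0.0992 and 0.402) and with midpoint matching (0.0924 and 0.0544), where the SDF-1 axis (0.0484), glycolysis (0.0227) and integrins (0.0198) passed. Lysosome genes were lost at the preset correlation (0.106), and actin genes and immune markers in Fisher's exact test (0.0992 and 0.238). Over genes at 1 FPKM or more, the 30 lists kept their side of the threshold.

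The lowest Pearson's r between libraries, 0.994, became 0.988 with a pseudocount of 0.1 and 0.990 over genes at 1 FPKM or more; leaving out each replicate leaves 1 pair, so the range from 0.994 to 0.997 is that of the 3 pairs and tests no stability. Of 147 named genes' levels, 146 moved by less than their SD under median-ratio scaling; THY1, listed at 0.03 FPKM in each library, has an SD of 0, which decides nothing. Without replicate 1 the mean of 6 levels fell more than 1.5 times: PSAT1 from 6.37 to 2.98 FPKM, SLC7A11 from 1.44 to 0.81, CCN1 from 20.5 to 11.6, ANKRD1 from 26.7 to 16.0, TAGLN from 10.0 to 6.67 and COL2A1 from 0.0167 to 0.01. No paired analysis was possible because the samples form 1 labelled group. Other splits of the samples were not run, since no monolayer library was analysed here. Depth is unknown, so low levels carry no floor, and 538 genes called higher and 504 called lower had a spheroid mean under 1 FPKM.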

Other observations

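Gene families by symbol were chosen after the data were seen and tested in the same way over 17 families, so their p-values are not independent evidence. The alternatives tried for the fixed lists were not run for the families. Some share members with the fixed lists: 8 of 41 chemokine genes, 3 of 38 kinesins, 3 of 21 centromere proteins, 17 of 45 histones, 1 of 19 S100 genes and 1 of 20 tubulins. Chemokine genes had 21 of 41 members higher and 2 lower, or 16 and 2 of the 33 outside the fixed lists (permutation adjusted p = 0.000486), with CXCL10 and CXCL11, ligands of a T-cell chemokine receptor, at log2 fold changes of 7.28 and 7.17 and the monocyte chemoattractant CCL8 at 7.04 in the authors' deposited table. The chemokine genes that were lower were CXCL14 at -1.36 and XCL1 at -1.47 in the authors' deposited table. Genes of MHC class I and II and antigen processing had 22 of 30 higher and none lower (permutation adjusted p = 0.000486), among them HLA-B at 1.87, B2M at 1.70, and the class II genes HLA-DRA and CD74 at 3.92 and 3.39 in the authors' deposited table. CXCL10 averaged 143 ± 14.5 FPKM, HLA-B 1986 ± 225 and HLA-DRA 25.1 ± 1.54 (SD, n = 3). The 7 guanylate-binding protein genes were higher, with a median of 2.82 in the authors' deposited table (permutation adjusted p = 0.000486). Type I and III interferon genes had none of 11 past the threshold and none above a mean of 1.86 FPKM (permutation adjusted p = 0.443).

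Complement and acute-phase genes had 14 of 23 higher and 1 lower (permutation adjusted p = 0.000486), with the iron-scavenging lipocalin gene LCN2 at 6.73, the complement factor gene CFB at 4.05 and C3 at 2.49, and with C5 lower at -2.45 in the authors' deposited table. Metallothionein genes had 6 of 8 higher (permutation adjusted p = 0.00189), including MT1X at 2.43 in the authors' deposited table. S100 genes did not pass as a family (5 of 19 higher; permutation adjusted p = 0.286), while the calprotectin genes S100A8 and S100A9 stood at 9.63 and 8.63 in the authors' deposited table, beside S100A7 at 6.14, S100A12 at 5.02 and S100A16 at 1.10. Centromere protein genes had 18 of 21 lower, or 15 of the 18 outside the fixed lists (permutation adjusted p = 0.000486), and Fanconi anaemia genes 7 of 10 lower (permutation adjusted p = 0.00085), and kinesin genes had 14 of 38 lower and 5 higher, namely KIF1A, KIF3C, KIF5C, KIF6 and KIF21B, with 11 of the lower genes outside the fixed lists (permutation adjusted p = 0.0402). Cytosolic aminoacyl-tRNA synthetase genes had 5 of 18 lower and a median of -0.73 in the authors' deposited table (permutation adjusted p = 0.000486), with VARS1 at -1.62, IARS1 at -1.47, EPRS1 at -1.21, MARS1 at -1.12 and YARS1 at -1.09, and the interferon-inducible WARS1 the one higher, at 1.26. The 46 proteasome genes lay slightly below random lists (median -0.10 in the authors' deposited table against 0.16, permutation adjusted p = 0.0343). Even so, 4 of them were called higher and 1 lower. The 4 higher were the immunoproteasome subunit genes PSMB8, PSMB9 and PSMB10 and the activator gene PSME1, and the assembly factor gene PSMG1 was lower. The replication-dependent histone family had 14 of 45 higher, 6 of them outside the fixed list, and 2 lower, H4C12 and H2AC14, both listed at 0 in the spheroids (permutation adjusted p = 0.000486). Among the 6, H4C14 and H4C15 had identical values in the 3 libraries, and H2AC19 was at 0 FPKM in replicate 3. The histone count and p-value treat such copies as separate genes. Tubulins had 2 of 20 higher, TUBA1A and TUBB8B, and 3 lower, TUBB4B, TUBG1 and TUBA3C. As a family they lay below random lists (median -0.31 in the authors' deposited table against 0.13, permutation adjusted p = 0.0402). Complex I subunits (none of 37; permutation adjusted p = 0.186), basement membrane genes (1 of 23 higher, LAMA5, and 6 lower; permutation adjusted p = 0.0596) and cancer-testis antigen genes (7 of 63 higher, 8 lower; permutation adjusted p = 0.976) did not pass.

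The tests of the next 3 patterns were all chosen after the results were seen. Inflammatory and interferon-stimulated genes were higher in spheroids, as were 4 immune cell markers. Immune cells mixed into the cultures would bring their abundant transcripts. The 14 markers, of which 6 reached 1 FPKM with CD68 (702 FPKM) and CD3D (32.6 FPKM) highest, had a median of 0.893 FPKM. The called inflammatory genes had a median of 32.0 FPKM. These medians decide nothing, since the markers belong to different immune cell types and the inflammatory genes were taken because they were called higher. PTPRC averaged 0.0233 FPKM and TYROBP was listed at 0, which argues against immune cells expressing these genes as the source. Separate handling of the monolayer and spheroid libraries cannot be told apart from culture form, since 0 monolayer samples with labels were at hand. The DMSO of the spheroids cannot be told apart from culture form either, since the treatment of the monolayer cultures is not given. A response of the chondrocyte line itself to growth in aggregates may be the source and stays a hypothesis without a test.

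Spheroid replicate 1 lay nearer to the monolayer state over the called genes: across 2799 of them at 1 FPKM or more, which are not independent, its deviation from the other libraries had a Spearman's rho of -0.52 with the authors' fold change, against 0.47 and 0.27 in replicates 2 and 3. The deviations of each gene sum to 0 over the libraries, so the values of replicates 2 and 3 are no independent contrast to replicate 1. Across all 12410 genes at 1 FPKM or more Spearman's rho was weaker, at -0.24, 0.31 and 0.05, with replicate 2 farther from 0 than replicate 1. A scaling error would move all genes one way, but the median deviation was 0.12 over genes lower in spheroids and -0.08 over genes higher, which argues against it. A single share of monolayer RNA in that library was examined too. It used called genes at 1 FPKM or more with an absolute log2 fold change of at least 2. Genes higher in spheroids would need a median share of 13.4% (95% bootstrap interval over 583 genes, 11.8 to 14.8). Genes lower would need 4.57% (4.09 to 5.41 over 334 genes). The medians differ, but the bootstrap treats genes of 1 library as independent, so the intervals are too narrow. They do not settle whether 1 share could serve both. A culture less advanced in the change from monolayer to spheroid could give this pattern in replicate 1 and was not tested.

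Replication-dependent histones were higher while the DNA replication genes were lower. Reads shared between near-identical copies would leave the summed level of a histone type unchanged. With monolayer levels taken from the authors' fold changes, its log2 ratio was 1.30 over 12 H2B copies (1.11 to 2.15 with any one left out). It was 0.97 over 3 H1 copies (0.96 to 1.54), a sum made mostly of H1-2 at 148 FPKM. These sums leave out 7 copies at 0 in the spheroids without a fold, whose monolayer level is unknown. They argue against sharing among the tested H2B copies as the whole cause. They decide nothing for H1, or for reads shared with the copies left out. Over 30 H2A, H3 and H4 copies the log2 ratio was 2.68. But 5 at 0 in the spheroids with a fold below 0 have no monolayer level in that sum, among them the 2 called lower. Sharing therefore cannot be told apart from a rise in the H2A, H3 and H4 types. More capture of RNA without a poly(A) tail in the spheroid libraries stays open too, with 2 of 45 family members called lower and other RNAs without a tail not analysed here, as does, untested, a candidate explanation in the cells, histone transcripts with a tail in cells that have left the cycle. In replicate 3 H2AC19 was listed at 0 FPKM, against 53.2 and 53.6 in replicates 1 and 2, while its near-identical copy H2AC18 was at 507 against 286 and 323.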
